A study of Homo sapiens with 4 samples.

How the data were processed

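RNA of MDAH2774 ovarian cancer cells was profiled in 4 samples, 2 controls that, per the labels, received no rhSTIP1 and 2 treated with 0.4 µM rhSTIP1, and the groups and array numbers were taken from the labels. What the controls received in its place is not stated. Per the labels' protocols, total RNA was extracted with TRIZOL, labelled with biotin and hybridised by the standard Affymetrix procedure. The values are signal intensity on a linear scale, 1 per probe set and array, as the authors deposited them. The submitters' processing notes name MAS5 and Affymetrix Expression Console 1.1. The value table has a mean after trimming 2% at each end close to 500 on every array (500.2), so the arrays had been scaled to a common level. The genome build, the annotation release and the MAS5 settings, detection calls included, are not given in the sources used here, and no coordinates are printed. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of arrays held identical values, and their Pearson correlations on the log2 scale lay between 0.932 and 0.957.

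Of 22283 probe sets, 68 Affymetrix controls were left out of the tests. Of the other 22215, 19065 had a single gene symbol in the platform annotation, 1043 had several and 2107 had none, and genes were named only from the first kind. Symbols were checked by gene identifier against a RefSeq gene table, which matched 19053 of them. Signals were transformed as log2(signal + 16), so fold changes are on that scale and understate the change of dim probe sets. Probe sets were kept when their mean over the 4 arrays reached the 40th percentile, a signal of about 85.3, which left 13329 probe sets, 11811 of them with a single symbol, for 8011 genes. A gene was represented by its brightest probe set with a single symbol, and where another tested probe set of a named gene had the opposite sign, its value, or the range where there were several, is given. Values of single genes are from the main settings over all 4 arrays unless said otherwise.

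rhSTIP1 and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and calls at an adjusted p of 0.05. All 4 arrays entered without covariates, which left 2 residual degrees of freedom and 6.93 prior degrees of freedom. The fit with the array number as a block has 1 residual degree of freedom and draws on 44.6 prior ones, so its p-values rest mainly on the spread pooled over probe sets. The labels do not say what a number shares. The BioC spike-in, though not BioB, BioDn or CreX, and many probe sets split the arrays by number, so the differences within each number and the blocked values are given for the main results. With 2 arrays against 2, an exact two-sided permutation test cannot go below p = 0.333, and 33.3% of unchanged probe sets would have groups that do not overlap. For that reason probe sets whose groups lay at least 1.5-fold apart were also counted, beside the same count in the other splits of the 4 arrays.

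The 23 gene lists were BMP-SMAD target genes, BMP receptor and SMAD components, TGF-beta target genes, ERK and immediate early genes, S phase genes, G2 and mitosis genes, p53 target genes, heat shock and HSP90 chaperone genes, NF-kB target genes, interferon-stimulated genes, unfolded protein and ATF4 response genes, hypoxia genes, cholesterol synthesis genes, MYC and ribosome biogenesis genes, ribosomal protein genes, oxidative phosphorylation genes, apoptosis regulators, epithelial and mesenchymal genes, and fibroblast, leukocyte, endothelial and mesothelial markers. They hold 417 genes, of which 365 were named on the array and 294 were tested. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 such lists, and again with an estimated correlation and with fry. With an estimated correlation, camera tests on the residual degrees of freedom alone, 2 without the block and 1 with it. A list can hardly pass such a test, so a call lost there does not show that correlated genes had made it. Standard errors of list means are over genes.

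The main tests, the gene lists and the rule for naming genes were fixed before the data were examined, as were most alternatives. The rule names STIP1, ACVR1, BMPR2, SMAD1, SMAD4, SMAD5, SMAD6, SMAD7 and ID1 to ID4. It adds the 10 genes with the largest rise and the 10 with the largest fall among those that passed, filled up, where fewer passed, by the smallest unadjusted p among genes whose groups lay at least 1.5-fold apart. It also takes up to 3 members of each list by the smallest unadjusted p. As 0 genes passed, all 20 places were filled in that way. A gene named outside the rule is said to be so.

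The alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, pseudocounts of 1 and 64, the number as a block, eBayes without a trend or robust, each array left out in turn, an adjusted p of 0.1, a 2-fold threshold, camera with an estimated correlation, and the mean of all probe sets of a gene. The median log2 difference over all tested probe sets was -0.012 as deposited, -5.74e-07 after quantile normalization and -0.013 after median centring.

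The tests were tried on simulated arrays with the means of the 13329 probe sets, 200 of them changed, in 10 draws for each kind of noise. The simulated arrays also carried the observed difference between the numbers, and their noise level was taken from the blocked fit. The higher recovery of the blocked fit below is thus partly built in and is no evidence for the block. With uneven noise between probe sets, the unblocked fit recovered 0%, 12.9% and 45.7% of changes of 2-fold, 4-fold and 8-fold, and 2.02% of its calls were false. The blocked fit recovered 1.20%, 36.4% and 62.8%, and 11.5% of its calls were false. With more even noise, the unblocked fit recovered 2.07%, 52.0% and 76.1% with 0% false calls, and the blocked fit 47.6%, 84.1% and 90.7% with 10.7% false calls. Of simulated lists of 10 genes shifted by 0.5 on the log2 scale, 93.5% and 100% were called, and of unshifted lists 1% and 2%. The simulated noise was independent between probe sets, so these shares do not cover lists whose genes move together.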

Results

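Gene expression was measured on 4 Affymetrix arrays in MDAH2774, a human ovarian cancer cell line. RNA came from 2 control samples and from 2 samples treated with 0.4 µM recombinant STIP1 (rhSTIP1 in the labels), a co-chaperone of the heat shock proteins that cells can also release. Each array gave a signal for 22283 probe sets, and 13329 of them were bright enough to be tested. The median signal was 155 and 163 on control arrays 1 and 2, and 150 and 157 on rhSTIP1 arrays 1 and 2. The number of arrays, 2 per group, limits the precision of every value. The ratio of 3' to 5' signal, a measure of RNA integrity, was 1.08 and 1.15 for GAPDH in the controls and 0.976 and 1.21 with rhSTIP1. For ACTB it was 1.28 and 1.28 in the controls and 1.20 and 1.27 with rhSTIP1, so the GAPDH ratios of the groups overlapped and the ACTB ratios were slightly lower with rhSTIP1. A control probe set for 28S ribosomal RNA did move with treatment, at a signal of 824 and 556 on control arrays and of 2766 and 1588 on rhSTIP1 arrays. The arrays also split by the number in their labels: the BioC spike-in read 959 and 1157 on the arrays numbered 1, and 367 and 270 on those numbered 2. The BioB, BioDn and CreX spike-ins did not split that way (BioB 303 and 388 on number 1, 369 and 253 on number 2). Differences within each number and fits with the number as a block are therefore given beside the main results, though not for every gene and list.

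The title of the series names SMAD signalling, and the first comparison asked whether SMAD-regulated genes differ after exposure to STIP1. ID1, ID2, ID3 and ID4, inhibitors of helix-loop-helix transcription factors and well-known targets of bone morphogenetic protein (BMP) signalling, were all higher on both rhSTIP1 arrays than on either control array. ID4 showed the widest gap, with a mean signal of 926 ± 585 (SD, n = 2) after rhSTIP1 and 84.7 ± 33.0 (SD, n = 2) in controls, an 8.65-fold difference. ID3 averaged 1416 ± 956 after rhSTIP1 and 297 ± 17.6 in controls, 4.03-fold higher. ID1 averaged 4543 ± 415 against 1667 ± 362, and ID2 993 ± 435 against 405 ± 21.7, which were differences of 2.74-fold and 2.28-fold.

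On the log2 scale the differences were 1.45 ± 0.22 (SE) for ID1, 1.19 ± 0.32 for ID2, 2.01 ± 0.42 for ID3 and 3.11 ± 0.47 for ID4. Within the arrays numbered 1 these genes differed by 1.32, 0.79, 1.33 and 2.09, and within the arrays numbered 2 by 1.58, 1.59, 2.69 and 4.13, in the same order. None of the 4 ID genes passed limma over all probe sets, where the adjusted p was 0.654 for ID1 and ID4 and 1.00 for ID2 and ID3. With the array number as a block, all of ID1 to ID4 passed, at limma adjusted p = 1.00e-06 for ID1, 0.0125 for ID2, 1.96e-06 for ID3 and 6.13e-07 for ID4, and 0 of the 4 passed in the blocked fit without an intensity trend in the variance. Without a block, ID3 and ID4 passed when rhSTIP1 array 1 was left out (limma adjusted p = 0.000159 each), a fit that assumes the lone rhSTIP1 array to vary like the controls, and no ID gene passed when any other array was left out. Other probe sets of ID4 were higher by 1.35 ± 0.64 and 2.19 ± 0.55 on the log2 scale, while the dimmer probe set of ID2 differed by -0.083 ± 0.61.

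**Figure D1:**
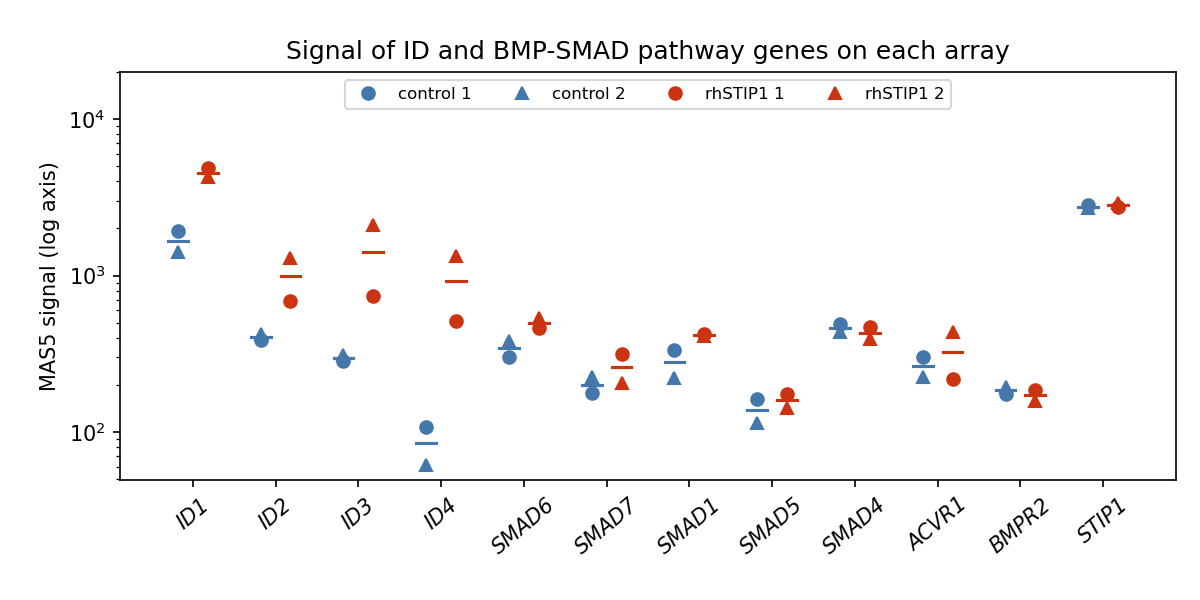
MAS5 signal (log axis) of the ID genes, the SMAD and receptor genes and STIP1 on each of the 4 arrays; blue marks controls, red marks rhSTIP1, circles and triangles the arrays numbered 1 and 2, and bars the mean of each group. ID1 to ID4 lie higher on both rhSTIP1 arrays than on either control array, with mean log2 differences of 1.19 to 3.11, while SMAD4, BMPR2 and STIP1 differ by -0.11, -0.11 and 0.042.

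The other SMAD pathway genes showed smaller differences, none of which passed the test with or without the block. SMAD6, an inhibitory SMAD induced by BMP signals, differed by 0.52 ± 0.27 on the log2 scale and was higher within both numbers, by 0.58 and 0.46. SMAD7, the other inhibitory SMAD, differed by 0.33 ± 0.36, with 0.77 within number 1 and -0.12 within number 2. The receptor-regulated SMAD1 differed by 0.58 ± 0.30 and SMAD5 by 0.20 ± 0.42, and the common partner SMAD4 by -0.11 ± 0.26. The receptor gene ACVR1 differed by 0.24 ± 0.38, with opposite signs within the numbers (-0.44 and 0.91), and BMPR2 by -0.11 ± 0.37. The transcript of STIP1 itself differed by 0.042 ± 0.19 at its brightest probe set and by 0.37 ± 0.22 at the other.

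As a group, the BMP-SMAD target genes rose: 10 of the 14 listed were tested, 7 were higher and 3 lower, and the mean log2 difference was 0.88 ± 0.34 (SE over genes), with camera adjusted p = 1.53e-09. With an estimated correlation between genes (0.074) camera gave an adjusted p of 0.511, a test on only 2 residual degrees of freedom. Fry gave an adjusted p of 0.333. Among the members, 0 passed over all genes and 4 passed adjusted over the list alone, and with the block 4 passed in both ways, in each case ID1 to ID4. This list was drawn up knowing that the study concerns ID3 and the SMAD proteins, so its count is not independent evidence of its direction. The mean was 0.71 within number 1 and 1.05 within number 2, and the block gave camera adjusted p = 5.90e-16 (adjusted p = 0.885 with an estimated correlation). Without ID1 to ID4 the remaining 6 genes had a mean of 0.17 and did not pass (camera adjusted p = 0.185, or 0.258 with the block).

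Genes of the BMP receptors, ligands and SMAD components did not shift together. Of the 13 tested, 6 were higher and 7 lower, with a mean log2 difference of 0.015 ± 0.12 (camera adjusted p = 0.929). The activin receptor gene ACVR2B differed by 0.90 ± 0.49 and ACVR2A by -0.40 ± 0.29. The 12 tested TGF-beta target genes had a mean of 0.037 ± 0.14 (camera adjusted p = 0.482), which changed sign between -0.21 without rhSTIP1 array 1 and 0.26 without rhSTIP1 array 2. With all arrays, KLF10 differed by 0.81 ± 0.34 and PMEPA1, a feedback inhibitor of TGF-beta signalling, by -0.97 ± 0.40. For both lists 0 members passed over all genes and 0 adjusted over the list alone.

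The comparison was then extended to all tested probe sets. After ID1, ID3 and ID4, the genes taken by the naming rule as higher after rhSTIP1 were SELENOT, a selenoprotein of the endoplasmic reticulum (2.12-fold), the mitochondrial carrier SLC25A16 (2.23-fold), the membrane glycoprotein HAVCR1 (2.39-fold), the apoptosis effector BAX (2.63-fold), the chromatin regulator ANKRD11 (3.95-fold), the folate receptor FOLR1 (1.90-fold) and the zinc finger gene ZNF358 (3.54-fold). HAVCR1 averaged 1470 ± 606 (SD, n = 2) against 583 ± 78.2 in controls. Those taken as lower were the potassium channel subunit KCNS1 (4.89-fold lower), the clathrin adaptor AP1S1 (2.08-fold lower), the JNK scaffold MAPK8IP2 (3.95-fold lower), the RNA-binding HNRNPUL2 (3.02-fold lower) and the prostaglandin synthase PTGDS (3.36-fold lower). The splicing factor SNRPF, the focal adhesion protein PXN, the transcription factor CEBPA, ADM2 and TMT1A were lower by 1.64-fold, 2.27-fold, 3.66-fold, 2.93-fold and 2.20-fold. KCNS1 averaged 52.5 ± 7.83 (SD, n = 2) after rhSTIP1 and 319 ± 37.1 in controls. In 8 of the 20 genes taken as higher or lower, namely ID4, ANKRD11, ZNF358, KCNS1, MAPK8IP2, PTGDS, CEBPA and ADM2, the mean of the dimmer group lay below the filter level of 85.3, and the size of the fold depends on the pseudocount. With a pseudocount of 64 or 1 in place of 16, the fold was 6.13 or 10.1 for ID4, 2.67 or 4.87 for ANKRD11 and 2.65 or 4.91 for MAPK8IP2.

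None of these genes passed the unblocked test. limma called 0 of 13329 probe sets, with a smallest adjusted p of 0.654, and 288 had an unadjusted p under 0.05 (162 higher and 126 lower). Evenly spread p-values would give 666, but the crossed split of the arrays, which mixes treatments and numbers, gave 300. Differences between the numbers stay in the residual of both fits, so 666 is not the count to expect of them. With the block, 728 had an unadjusted limma p under 0.05 (364 higher and 364 lower). With the array number as a block limma called 23 probe sets, 17 higher and 6 lower, of which 19 had a single gene symbol. The crossed split of the same arrays gave 0 under the same block. The only residual of that crossed fit is the treatment difference, so its 0 is not an independent check on the 23 calls. The blocked calls held ID1 to ID4, SELENOT (adjusted p = 0.00352), SLC25A16 (0.00528), HAVCR1 (0.00271) and FOLR1 (0.0309) among the higher genes, and KCNS1 (0.0260), AP1S1 (0.0138) and HNRNPUL2 (0.0230) among the lower ones. The other blocked calls with a symbol, named here after their values were seen, were 1 probe set each of SRRM2, DAZAP2, IPO5, NIBAN1, FEZ2, HUWE1 and ZFX, which were higher, and of the laminin chain LAMA5, which was lower. For 5 of these the call was not at the brightest probe set, which differed by -0.13 for SRRM2, 0.028 for DAZAP2, 0.14 for IPO5, 0.23 for NIBAN1 and 0.013 for FEZ2, and the dimmer HUWE1 probe set differed by -0.49. Within number 1 and number 2, KCNS1 differed by -2.52 and -2.06, AP1S1 by -0.66 and -1.45, HAVCR1 by 0.69 and 1.82 and SELENOT by 0.95 and 1.22. In simulated data of this design with 200 changed probe sets, 10.7% to 11.5% of the blocked calls were false, above the 5% aimed at. That share depends on how many probe sets truly change, so it is not an estimate for the 23 calls here. The blocked count fell to 0 without an intensity trend in the variance.

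Probe sets of the same gene often differed in direction: of 29 genes named by the rule that had other tested probe sets, 14 had at least 1 of opposite sign. BAX had a log2 difference of 1.40 ± 0.35 at its brightest probe set and -0.056 ± 0.61 at the other, and FOLR1 differed by 0.92 ± 0.24 and -1.17 ± 0.57. SLC25A16 differed by 1.16 ± 0.25 at its brightest probe set and by -0.44 ± 0.48 and -0.11 ± 0.49 at the rest, whereas all probe sets of AP1S1 were lower (-1.06, -0.78 and -0.46). PXN differed by -1.18 ± 0.33 and 0.033 ± 0.49, and IL1B by -1.02 ± 0.69 and 0.022 ± 0.62. PTGDS differed by -1.75 ± 0.45 at its brightest probe set and by -0.0027 ± 0.54 and -0.91 ± 0.74 at the rest. Of the 10 genes named for a rise, 4 had further tested probe sets, and in 1 of them, ID4, all of these were higher by at least 1.5-fold. Of the 10 named for a fall, 3 had further tested probe sets, and in 0 were all of these lower by as much.

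A count without a test gave no excess for treatment. Of the tested probe sets, 171 had both rhSTIP1 arrays at least 1.5-fold above (88) or below (83) both control arrays. The crossed split, which mixes treatments and numbers, gave 173, and the split by number gave 514. At 2-fold the counts were 37, 33 and 157. Across probe sets, which are not independent replicates, the differences within number 1 and within number 2 had a Pearson correlation of -0.0083, and 48.5% of probe sets had the same sign in both.

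**Figure D2:**
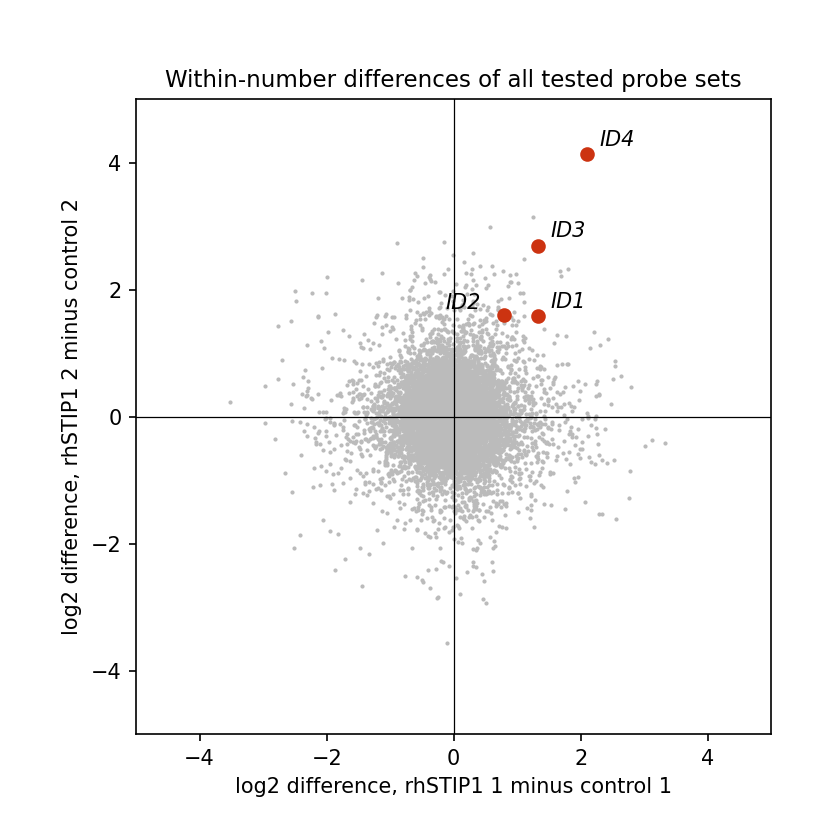
Each of the 13329 tested probe sets is a point at its log2 difference between rhSTIP1 and control on the arrays numbered 1 (x axis) and on those numbered 2 (y axis); red marks ID1 to ID4. The cloud has no slope (correlation -0.0083), and ID4 lies at 2.09 and 4.13.

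Beyond the SMAD lists, the cholesterol synthesis genes (camera adjusted p = 0.000603) and the apoptosis regulators (camera adjusted p = 0.0346) rose as groups at the preset correlation, by small amounts. Neither passed with an estimated correlation, on 2 residual degrees of freedom (adjusted p = 0.511 for the cholesterol genes and 0.626 for the apoptosis regulators). The estimated correlations, 0.0035 and -0.083, lay below the preset 0.01, so correlation between the genes did not end these calls. All 12 tested cholesterol synthesis genes were higher, with a mean log2 difference of 0.23 ± 0.039 (SE over genes). These are values of the brightest probe sets. Examples are the lathosterol oxidase SC5D (0.44 ± 0.21, but -0.51 ± 0.34 at its other probe set), FDPS (0.34 ± 0.19) and the squalene epoxidase SQLE (0.31 ± 0.19). Among 13 apoptosis regulators 8 were higher and 5 lower, with a mean of 0.21 ± 0.14. The members with the smallest p were BAX (1.40 ± 0.35, but -0.056 ± 0.61 at its other probe set), the initiator caspase CASP8 (0.73 ± 0.25) and PMAIP1 (0.57 ± 0.26), none of which passed over all genes.

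Camera called 3 of the 19 lists with at least 5 tested genes, namely the BMP-SMAD targets, the cholesterol synthesis genes and the apoptosis regulators. With an estimated correlation, on 2 residual degrees of freedom, 0 lists were called. The means were 0.31 and 0.16 within numbers 1 and 2 for the cholesterol genes, and 0.26 and 0.16 for the apoptosis regulators, and the block called both (adjusted p = 0.000131 and 0.0459, and adjusted p = 0.885 for each with the block and an estimated correlation). Of cholesterol members, 0 passed over all genes and 0 adjusted over the list alone. Of apoptosis regulators, 0 passed over all genes and 1, BAX, adjusted over the list alone (2 with the block). Fry, which asks whether a list moves on balance one way, called 0 lists, and its test for changes in either direction called 2, the p53 targets (adjusted p = 0.0145) and the apoptosis regulators (adjusted p = 0.0307), both of which hold BAX. The cholesterol mean was 0.11 without control array 1, which ended the call (adjusted p = 0.311), and 0.37 without control array 2, and the apoptosis call ended without control array 1, rhSTIP1 array 1 or rhSTIP1 array 2 (adjusted p = 0.340, 0.384 and 0.318). The apoptosis call also ended with no filter (0.0608), the stricter filter (0.0684) or the mean of all probe sets of a gene (0.0628).

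**Figure D3:**
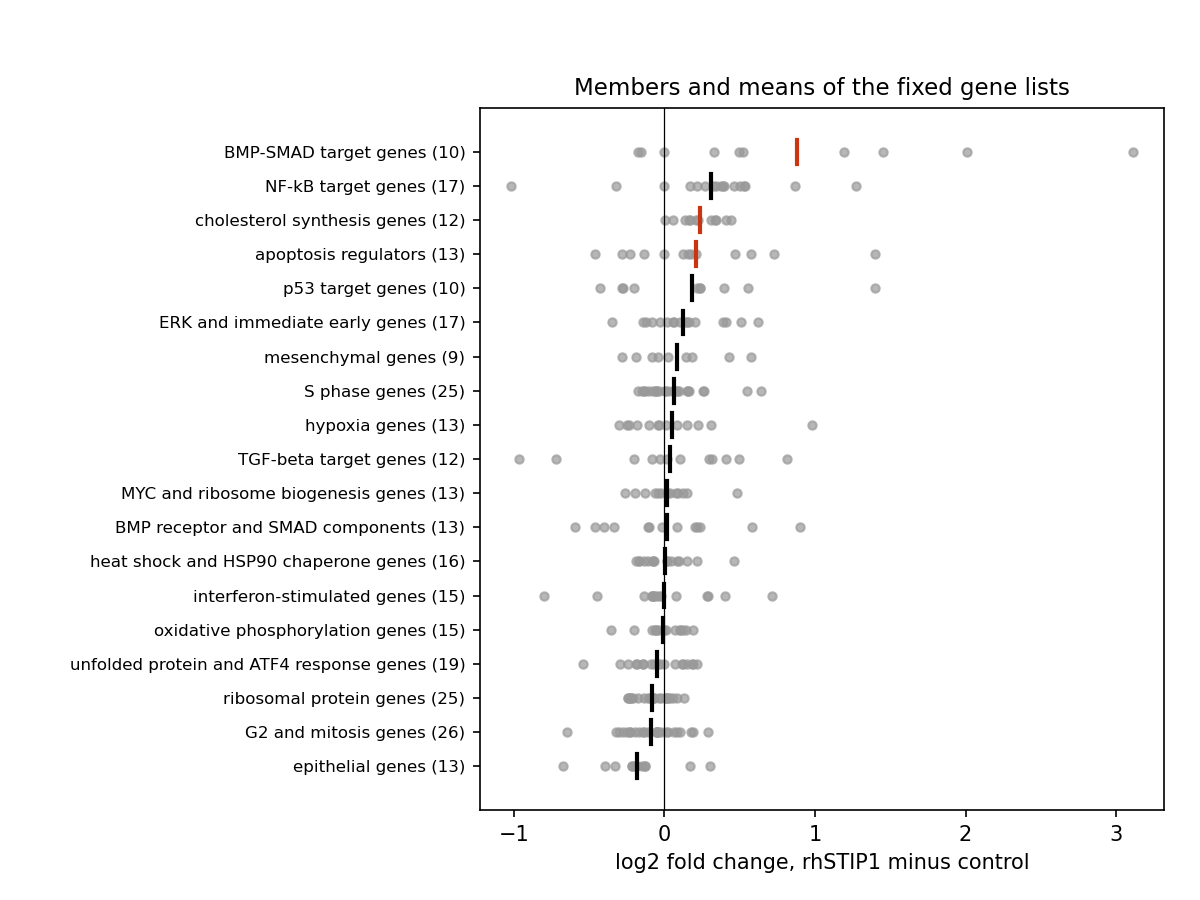
Log2 difference between rhSTIP1 and control for each tested member (grey points) of the 19 tested gene lists, with the number of members in brackets; bars mark the list mean, in red where camera called the list. The BMP-SMAD targets have the highest mean (0.88), followed by NF-kB targets (0.31) and cholesterol synthesis genes (0.23), and the means of the interferon-stimulated and ribosomal protein genes turn from below to above 0 with quantile normalization.

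NF-kB target genes, which encode chemokines, cytokines and their regulators, had the second highest mean, but its sign differed between the numbers. Of 17 tested, 14 were higher and 3 lower, with a mean of 0.31 ± 0.12. Within number 1 the mean was 0.78 ± 0.14 and within number 2 it was -0.15 ± 0.19. The interleukin gene IL1B differed by 0.44 within number 1 and -2.48 within number 2, ICAM1 by 0.46 and 0.46, and LIF by 0.83 and -0.042. Camera gave an adjusted p of 0.0589 without the block and 0.000117 with it (adjusted p = 0.885 with the block and an estimated correlation). It also passed without the block under the 60th percentile filter (adjusted p = 0.0484) and a pseudocount of 64 (0.0422), but not with an estimated correlation (adjusted p = 0.786). The correlation estimated between these genes without the block was 0.281, far above the preset 0.01. Camera p-values for this list at the preset correlation may therefore be too small. The list mean was -0.49 without rhSTIP1 array 1 and 1.22 without rhSTIP1 array 2, each with a lone rhSTIP1 array left. Of its members 0 passed over all genes and 0 adjusted over the list alone, or 1 adjusted over the list alone with the block.

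Proliferation genes did not pass at the main settings. The 25 tested S phase genes had a mean of 0.064 ± 0.040 (adjusted p = 0.415), which was 0.020 without control array 1 and 0.14 without rhSTIP1 array 2, with TK1 at 0.55 ± 0.25, CCNE2 at 0.64 ± 0.51 and RRM2 at 0.25 ± 0.20 (-0.13 ± 0.20 at its other probe set). The 26 genes of G2 and mitosis had a mean of -0.090 ± 0.038 (adjusted p = 0.184), which was -0.014 without rhSTIP1 array 1 and -0.17 without rhSTIP1 array 2, with CENPE at -0.65 ± 0.30, PLK1 at -0.30 ± 0.20 and KIF20A at -0.25 ± 0.20. Genes of ERK and immediate early signalling averaged 0.12 ± 0.060 over 17 members (adjusted p = 0.131), with JUN at 0.62 ± 0.35, DUSP1 at 0.51 ± 0.25 and JUNB at 0.41 ± 0.27. That list passed with the mean of all probe sets of a gene (mean 0.21, adjusted p = 0.0255) and without control array 2 (mean 0.27, adjusted p = 0.00481). It did not pass with an estimated correlation (adjusted p = 0.786), and the mean was -0.046 without control array 1. The p53 targets averaged 0.18 ± 0.17 over 10 members (adjusted p = 0.131), 0.029 without rhSTIP1 array 1 and 0.080 with the mean of all probe sets. At the main settings GADD45A differed by 0.56 ± 0.25, XPC by -0.43 ± 0.24, and BAX passed adjusted over the list alone. MYC and ribosome biogenesis genes averaged 0.020 ± 0.052 over 13 members (adjusted p = 0.898), with NIP7 at 0.48 ± 0.36, POLR1B at -0.27 ± 0.30 and NOP16 at -0.20 ± 0.22 (0.11 ± 0.26 at its other probe set).

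Stress and metabolic lists did not pass at the main settings. The 16 heat shock and HSP90 chaperone genes, the family in which STIP1 works, averaged 0.0056 ± 0.043 (adjusted p = 0.902), with CDC37 at 0.46 ± 0.21, FKBP4 at 0.21 ± 0.20 and HSP90AB1 at -0.17 ± 0.17 (-0.069 ± 0.22 and 0.0046 ± 0.19 at their other probe sets). The unfolded protein and ATF4 response averaged -0.048 ± 0.045 (adjusted p = 0.898), with CALR at -0.54 ± 0.26, SDF2L1 at -0.30 ± 0.23 and CEBPB at 0.19 ± 0.20. Hypoxia genes averaged 0.047 ± 0.094 (adjusted p = 0.943), -0.28 without a filter and 0.19 without control array 2, with ANGPTL4 at 0.98 ± 0.59, PFKFB3 at -0.30 ± 0.31 and LDHA at -0.23 ± 0.19. Oxidative phosphorylation genes averaged -0.0082 ± 0.037 (adjusted p = 0.943), with NDUFS3 at -0.36 ± 0.19, COX5A at 0.19 ± 0.20 and SDHA at -0.20 ± 0.23. Interferon-stimulated genes averaged -0.0041 ± 0.091 (adjusted p = 0.929) and 0.014 with quantile normalization, -0.16 without a filter and -0.27 without control array 2, with IFIT3 at -0.80 ± 0.62, OAS1 at 0.71 ± 0.67 and IRF9 at 0.40 ± 0.32. Ribosomal protein genes averaged -0.080 ± 0.022 over 25 members (adjusted p = 0.131) and 0.014 with quantile normalization, with RPS3, RPS4X and RPL14 at -0.24, -0.23 and -0.23. The sign of the list mean differed between the numbers, at 0.058 ± 0.021 within number 1 and -0.22 ± 0.037 within number 2. Without rhSTIP1 array 1 the ribosomal protein list passed as lower (mean -0.16, adjusted p = 0.00422), whereas the mean was -0.0043 without rhSTIP1 array 2. With an estimated correlation (0.362) all arrays gave an adjusted p of 0.948 for it.

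Epithelial genes averaged -0.18 ± 0.066 over 13 members, 11 of them lower (adjusted p = 0.184), and from -0.28 without control array 1 to -0.057 without rhSTIP1 array 1, with KRT19 at 0.30 ± 0.19, CLDN7 at -0.68 ± 0.60 and the ovarian cancer lineage factor PAX8 at -0.19 ± 0.18, whose other probe sets ranged from -0.098 to 0.88. Mesenchymal genes averaged 0.084 ± 0.094 over 9 members (adjusted p = 0.898), -0.14 without a filter, -0.21 without control array 2 and 0.35 without control array 1, with MMP14 at 0.58 ± 0.50 (-0.19 ± 0.56 at its other probe set), MMP2 at 0.43 ± 0.47 and ZEB1 at -0.28 ± 0.39. In 5 lists, the BMP receptor and SMAD components, heat shock, interferon, hypoxia and oxidative phosphorylation genes, the mean, the median and the direction of the test differed in sign. Apart from the lists whose members are counted above, 0 members of any list passed over all genes or adjusted over the list alone without the block. Markers of other cell types were too few past the filter for a test. The fibroblast marker COL1A1 differed by -0.63 ± 0.50, the leukocyte markers CD74 and ITGAM by -0.14 ± 0.20 and -0.30 ± 0.48, the endothelial markers PECAM1 and ERG by -0.75 ± 0.46 and -0.48 ± 0.57 (the other PECAM1 probe set by 1.08 ± 0.64), and the mesothelial markers CALB2 and WT1 by 0.26 ± 0.42 and 0.18 ± 0.41. With the block, camera called 4 lists, the 3 above and the NF-kB targets.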

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

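Control probe sets were outside the comparisons of the report, and 34 of them reached the signal level of the filter. In 2 of these, both rhSTIP1 arrays lay at least 1.5-fold above both control arrays, and in 0 at least 1.5-fold below. The older 28S ribosomal RNA control, at its middle probe set, read 824 and 556 on the control arrays and 2766 and 1588 on the rhSTIP1 arrays, a ratio of means of 3.16. The newer 28S ribosomal RNA control, at its 3' probe set, read 168 and 237 on the control arrays and 545 and 425 on the rhSTIP1 arrays, a ratio of 2.40. No biological explanation was tested for either.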

How the results depend on the processing

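The replicate block combined with another setting, and the BMP-SMAD list without ID1 to ID4, were tests chosen after the data were seen. The count of called probe sets (0) was kept under both normalizations, both filters, both other pseudocounts, eBayes without a trend or robust, and an adjusted p of 0.1, with smallest adjusted p between 0.417 and 1.00. Leaving out each array gave 0 to 3 calls, with 3 without rhSTIP1 array 1 and 2 without rhSTIP1 array 2, fits that assume a lone rhSTIP1 array to vary like the controls. The replicate block gave 23, and with the block the count was 4 without a filter, 6 with the 60th percentile filter, 41 with quantile normalization, 16 with a pseudocount of 1, 9 with a pseudocount of 64 and 0 without an intensity trend. Deviations of same-numbered arrays from their group means had a correlation of 0.236 across probe sets, and the labels do not pair the arrays.

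The count of probe sets apart by 1.5-fold (171) became 1524 without a filter and 21 with the 60th percentile filter, which change the number tested, 107 with a pseudocount of 64, 37 at 2-fold, and 778 to 1201 with an array left out, where a group of 1 array makes separation easier.

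The BMP-SMAD mean of 0.88 kept its camera call at the preset correlation under the settings run with the full list (0.69 to 1.07 with an array left out). With an estimated correlation it stayed at 0.88 without passing (adjusted p = 0.511, or 0.885 with the block), fry did not pass it (adjusted p = 0.333), and without ID1 to ID4 it was 0.17 (adjusted p = 0.185, or 0.258 with the block). The count of called lists (3) was 0 with an estimated correlation and 1 to 4 with an array left out, with 1 without control array 1; the cause was not tested. In 11 of the 19 lists, 0 of them called at the main settings, the mean changed sign when some array was left out, and in 18 it changed sign or moved by over 1.5 times. Robust eBayes was not run for lists. Over the named genes, 1060 values kept their direction and side of the threshold and 13 passed where they had not before, 11 of them under the block. With an array left out, 3 reversed: OAS1 ranged from -0.038 to 1.18 and MMP14 from -0.17 to 1.32 where tested, each lowest without control array 2, and CLDN7 from -1.54 to 0.19, highest without rhSTIP1 array 1. The cause was not tested. Dim probe sets near the filter level of 85.3 limit what 2 arrays per group can show.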

Other observations

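The contrasts by array number below and the naming of genes in them were chosen after the results were seen. So were the tests of the other ID4 probe sets and of the NF-kB targets within numbers. The genes named are a selection from those with the smallest p in each direction, and others such as GAL3ST1, MYO10 and PALLD are left out. LIF was added outside that selection. The number is not a group of the study. The chemokine genes CXCL1 and CXCL2 and the cytokine gene TNF were lower on the arrays numbered 2 than on those numbered 1, by 30.8-fold, 9.09-fold and 6.60-fold, while the cytokine gene LIF was not (mean signal 864 on number 1 and 957 on number 2). CXCL1 averaged 5936 ± 4175 (SD, n = 2) on the arrays numbered 1 and 160 ± 74.2 on those numbered 2. Each number holds a control and an rhSTIP1 array, so an SD over a number includes any difference with treatment. The NF-kB targets had a mean log2 difference of -1.19, number 2 minus number 1, with 6 of 17 members called by limma (camera adjusted p = 1.57e-05, and adjusted p = 0.612 with an estimated correlation). The retinoic acid binding protein CRABP2 was lower by 7.56-fold, the matrix genes TGFBI and FN1 by 4.50-fold and 2.73-fold, and the caveolar coat gene CAV1 by 2.49-fold.

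Higher on the arrays numbered 2 were the hormone somatostatin, SST (6.58-fold, from 297 ± 69.2 to 2022 ± 100.4), the guanine nucleotide exchange factor VAV3 (6.91-fold), the urogenital lineage factor PAX2 (3.96-fold), FGF18 (5.60-fold), the uroplakin UPK1B (3.02-fold) and the amino acid transporter subunit SLC3A1 (18.7-fold, from a dim 36.2 ± 35.3). In all, limma called 170 probe sets between the numbers, 106 higher and 64 lower on number 2. At their brightest probe sets 104 genes were called, 61 higher and 43 lower, and further genes were called only at another probe set. The treatment split gave 0 calls and the crossed split 0.

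The rise of ID1, ID2, ID3 and ID4 on both rhSTIP1 arrays was set against technical explanations. Scaling of the arrays would need the differences to shrink with another scaling, and the smallest was 1.19 under quantile normalization or median centring, as in the deposited values. The deposited arrays already shared a common level, so these rescalings could change little and were a weak test. A faulty ID4 probe set would leave its other probe sets level, and their mean was higher by 3.26 times its standard error. That check covers ID4 alone. ID1 and ID3 had 1 tested probe set each, and the dimmer probe set of ID2 did not rise (-0.083 ± 0.61). A response of the ID genes to rhSTIP1, or to anything else in the protein preparation, may explain the rise as a hypothesis, and a technical difference that follows treatment, such as that in 28S ribosomal RNA signal, stays open.

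Many of the probe sets set apart by 1.5-fold between rhSTIP1 and control may reflect noise of single probe sets rather than a change of the gene. Of 81 such genes with further tested probe sets, 42 had the mean of these moving the same way, or 51.9% (95% Wilson interval 41.1% to 62.4%), close to the 51.5% of the crossed split. Between the array numbers the share was 81.2% (75.2% to 86.1%), which argues against the same explanation there. ID4 and AP1S1 were among the genes whose other probe sets moved the same way with treatment.

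NF-kB targets had a positive mean with rhSTIP1, and a response to the protein preparation in both numbers could be a candidate explanation. Their mean was 0.78 ± 0.14 (SE over genes) within number 1 and -0.15 ± 0.19 within number 2. The value within number 2 lies within its error of 0, so such a response is neither shown nor excluded there, and a difference between numbers in how far these genes can move was not tested.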
